A study of Mus musculus with 2 samples.

How the data were processed

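Total RNA from glomeruli dissected from male KK/Ta mice was hybridised to Affymetrix Mouse Genome 430 2.0 arrays. The arrays carry oligonucleotide probe sets, each a group of short probes for 1 transcript. Mice were 20 weeks old and had received a high-fat diet (HFD) or a normal chow diet (Chow). Each diet is represented by 1 array. The series design text speaks of 3 mice, and the labels do not say whether 3 animals stood behind each array, nor whether their RNA was pooled. RNA was purified on Qiagen RNeasy columns and amplified by two-cycle labelling to biotin-labelled cRNA, per the labels' protocols. The design text names GeneSpring 7.3.1 for the comparison of the diets. How probe intensities were summarised into probe set values, and how the arrays were scaled, is not given in the sources used here.

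The deposited values are linear probe set intensities, 1 column per array, with 45101 probe sets including 64 control probe sets. They ran from 0.0534 to 19489 on the HFD array and from 0.0539 to 19853 on the Chow array, so no log scale had been applied. The mean after removing 2% of values at each end was 292 on the HFD array and 300 on the Chow array, so the authors' values were already close to a common scale. The file gave no detection calls and no probe-level data. Two-cycle amplification and a design with 1 array per diet leave technical and biological differences between the libraries unseparated in every value.

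Control probe sets were set aside, values were put on a log2 scale, and each array was centred on the median of its 45037 remaining probe sets. Centring added 0.083 to every HFD minus Chow log2 difference. A floor was set at each array's 50th percentile (a deposited signal of 42.3 for HFD and 44.9 for Chow), and values under the floor were raised to it before differences were taken. A gene above the floor on 1 array only therefore has a bound, written as at least N-fold. Gene names came from the platform annotation of 2016: 34945 probe sets named 1 gene, 932 named several and 9160 were unnamed here. Of the probe sets with 1 gene, 34741 had an Entrez identifier in the RefSeq table of assembly GRCm38.p6, and 0 symbols changed through it. Gene spans in that table served 1 test of gene length, and no coordinates are printed. A gene was represented by its probe set with the highest mean over both arrays. Of 18193 genes, 11356 were above the floor on at least 1 array and 10824 on both.

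With 1 array per diet there is no replicate check, and no p-value, standard error or test between the diets is given. Genes were counted by a rule of size, at least 2-fold. The precision was described by the scatter of HFD minus Chow differences over genes of like signal (scaled median absolute deviation): it was 0.37 log2 units in the dimmest 10% of genes above the floor on both arrays and 0.14 in the brightest 10%. This scatter holds technical noise and real differences together. Gene lists, 27 in all (11 of cell type markers and 16 of pathways), were compared by the median difference of their members above the floor. Each median was set against 10000 random lists of the same size, matched on mean signal in 20 bins, and the central 95% of those medians is called the matched range. This describes these 2 arrays and does not test the diet. Genes are not independent replicates. Over all genes above the floor the median difference was 0.064 after centring, so counts of members above 0 are not to be set against an even split.

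The genes named were fixed by rule. With predicted genes, clone names and open reading frame names left out, the rule took the 12 largest differences in each direction among genes above the floor on both arrays whose further probe sets above the floor went the same way. It then took the 4 largest bounds in each direction, and up to 4 members of each list with the largest difference. H2-Aa, Lyz2, Adgre1, Coro1a, Cd68, C1qb, Mrc1, Fcer1g, Nphs1, Podxl, Postn, Cyp4b1, Pcx, Sec61b, S100a6, Slc13a1 and Laptm5 were named after their values were seen. The gene lists, the naming rule, the floor, the threshold and the alternatives below were chosen before the data were examined. The alternatives were no centring, quantile normalization, a loess fit of the difference on the mean signal (span 0.3), floors at the 30th and 70th percentile, no floor, the median over a gene's probe sets, leaving out probe sets that may match several transcripts, thresholds of 1.5-fold and 3-fold, and adding each array's 25th percentile before the log2 with no floor.

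The procedure was tested on simulated data for the HFD against Chow comparison, with 50 genes changed at each size among 11424 genes. The changed genes were drawn from those above the floor on both real arrays. Recovery was therefore not tested for genes above the floor on 1 array only. The procedure called 96% of genes changed 3-fold, 90% of those changed 4-fold, 54% of those changed 2-fold and 2% of those changed 1.5-fold. The recovery accepted for 3-fold and 4-fold changes, first set above 90%, was lowered to above 80% after 90% had been found at 4-fold. In 100 simulated pairs of unchanged arrays, a mean of 16.6 genes passed as at least 2-fold higher (range 9 to 27). A mean of 17.0 passed as at least 2-fold lower (range 7 to 29). The simulated scatter was normal around 0, with the scaled median absolute deviation of the real differences at like signal. Wider tails were not simulated. A simulated list shifted by 0.5 log2 units came out at 0.52. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.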

Results

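Gene expression was measured in glomeruli, the filtering units of the kidney, isolated from 20-week-old male KK/Ta mice. KK/Ta is an inbred strain that develops obesity and type 2 diabetes. The series compared a high-fat diet (HFD, 1 array) with a normal chow diet (Chow, 1 array). Values below are single measurements without replicates, so each difference describes these 2 RNA preparations. The log2 signals of both arrays correlated across probe sets with r = 0.945, and with r = 0.986 over probe sets in the brighter part of the range (mean above the median). Probe sets are not independent replicates. The spiked hybridisation controls differed by a median of -0.0011 log2 units between the arrays after centring, and the spiked poly-A RNAs by -0.15 (range -0.67 to 0.39). The 19 control probe sets for mouse transcripts differed by a median of 0.24, those of Gapdh by 0.20 to 0.28 and those of beta-actin by 0.14 to 0.28. The 19 ran from -0.98 to 1.83. Some, such as those of the transferrin receptor, were under the floor, and those named for murine B1 and B2 differed by -0.14 to -0.034. All genes above the floor had a median of 0.064, so 0.24 is no general shift. List medians of that size or smaller are to be read beside these control values. The ratio of 3′ to 5′ signal, a measure of RNA integrity and labelling length, was 3.43 (HFD) and 3.59 (Chow) for Gapdh. It was 1.72 and 1.89 for beta-actin.

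Glomerular RNA from HFD-fed mice held more transcript of macrophage and antigen presentation genes than RNA from Chow-fed mice. Of 11356 genes above the floor, 82 (0.722%) were at least 2-fold higher in HFD and 18 (0.159%) were at least 2-fold lower. Among genes above the floor on both arrays whose probe sets agreed in direction, the 4 largest positive differences were those of leukocyte genes: H2-Eb1 (3.88-fold) and Cd74 (3.58-fold), both of MHC class II antigen presentation, Cybb (3.46-fold), a subunit of the phagocyte NADPH oxidase, and Ptprc (3.32-fold), the pan-leukocyte antigen CD45. That rule left out the sulphate transporter gene Slc13a1 (3.51-fold) and Laptm5 (3.42-fold), whose probe sets disagreed in direction. Both differences were larger than that of Ptprc. The 82 higher genes lay above the range of 9 to 27 seen in simulated unchanged pairs, whereas the 18 lower genes lay within the corresponding range of 7 to 29. Among genes with a mean signal more than 2-fold over the array median, both counts lay above the simulated ones: 60 were higher (simulated range 0 to 7) and 11 lower (0 to 5). The simulated scatter was normal and centred on 0, whereas real genes above the floor had a median of 0.064 after centring. Without centring, 62 genes were higher and 23 lower. The simulated ranges therefore do not settle how many genes would pass by scatter alone, nor the imbalance between directions.

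**Figure D1:**
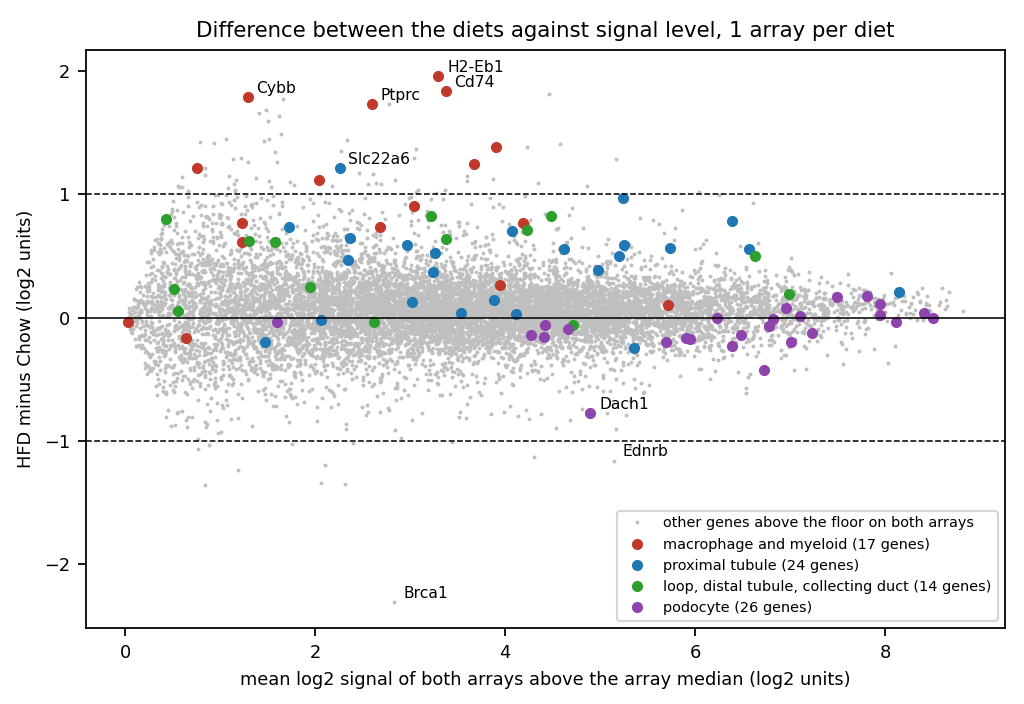
Each point is a gene above the floor on both arrays; the x axis is its mean log2 signal above the array median and the y axis its HFD minus Chow difference in log2 units, 1 array per diet, with dashed lines at 2-fold. The myeloid genes H2-Eb1 (1.96) and Cd74 (1.84) lie highest, proximal and distal tubule markers lie mostly above 0, podocyte markers lie close to or below 0, and Brca1 is lowest at -2.31.

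The other 8 of the 12 such genes with the largest positive difference also included leukocyte genes. Chil3, a secreted product of alternatively activated macrophages, was 3.10-fold higher (deposited signal 229 in HFD and 78.3 in Chow). Itgb2, the leukocyte integrin beta-2 chain, was 2.81-fold higher. Adgre4, a myeloid adhesion receptor, was 2.73-fold higher, and Lgals3, encoding galectin-3, was 2.73-fold higher. Epithelial genes stood beside them: Cdh1, encoding E-cadherin of tubule epithelium, was 3.16-fold higher and Ccl28, an epithelial chemokine, 3.02-fold higher. Tmem178 was 3.32-fold higher and Mob3b 3.21-fold higher. Each of these 12 genes had 1 probe set above the floor on both arrays. Among genes above the floor in HFD only, Cntn1 was at least 5.45-fold higher, Frzb, a secreted Wnt antagonist, at least 3.86-fold, Rdh16f2 at least 3.03-fold and Selplg, the leukocyte ligand of P-selectin, at least 2.93-fold.

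The largest negative difference was that of Brca1, a DNA repair gene, with a deposited signal of 136 in HFD and 711 in Chow (4.95-fold lower). A second Brca1 probe set, above the floor in Chow only, differed by -1.70 log2 units before the floor was applied, and 2 more, under the floor on both arrays, by -1.93 and 0.37. Ednrb, the endothelin B receptor, was 2.24-fold lower (1000 against 2369), and all 3 of its probe sets above the floor were lower. Adra2c, an adrenergic receptor, was 2.56-fold lower, Fgfbp1 2.54-fold, Ttc39c 2.35-fold and Gmnn, encoding the replication licensing inhibitor geminin, 2.28-fold lower. Uqcr11, a small subunit of respiratory complex III, was 2.19-fold lower and Nop10, a small nucleolar ribonucleoprotein, 2.05-fold lower. Fam171a2, Pnmal2 and Krt80 were lower by 2.04-fold, 2.03-fold and 2.01-fold, and Rps27 by 1.98-fold. Among genes above the floor in Chow only, Pnmt was at least 4.47-fold lower, Car3 at least 3.08-fold, Zfp956 at least 2.03-fold and Pllp at least 2.01-fold.

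**Figure D2:**
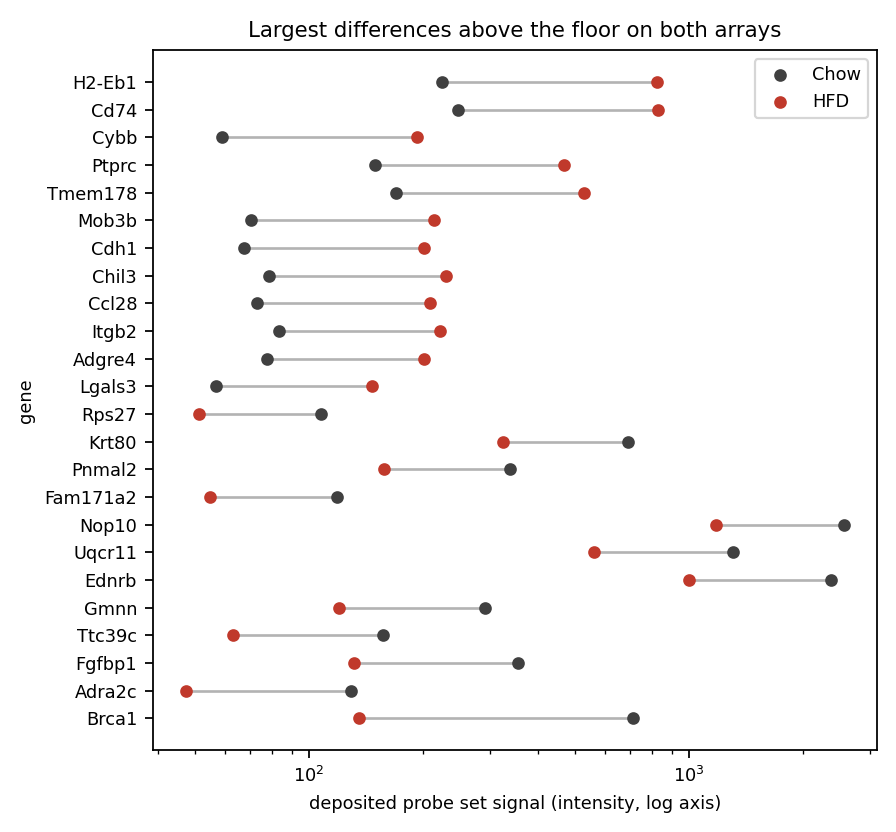
Deposited probe set signal (intensity, log axis) of the 12 genes with the largest positive and the 12 with the largest negative difference among those above the floor on both arrays whose probe sets agreed, with 1 point per diet and a line joining them. H2-Eb1 stood at 821 in HFD and 224 in Chow, and Brca1 at 136 and 711.

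Macrophage and myeloid markers formed the list with the highest median. Of its 22 members above the floor, 10 were at least 2-fold higher, 0 were at least 2-fold lower and 20 were higher by any amount. The median difference was 0.85 log2 units, against a matched range of -0.054 to 0.19, and it lay above all 10000 random lists. Beside H2-Eb1, Cd74, Cybb and Ptprc, the 2-fold members were H2-Aa (2.61-fold), Lyz2 (2.37-fold), Adgre1 (2.32-fold), which encodes the macrophage marker F4/80, Coro1a (2.17-fold), and, as bounds, Cd68 (at least 2.42-fold) and C1qb (at least 2.22-fold). Mrc1 differed by only 0.10 log2 units and Fcer1g by -0.16. Of the T and B lymphocyte markers 3 were above the floor, with Ighm at 0.54, Jchain at 0.36 and Cd8a at -0.18, and their median of 0.36 lay within the matched range (0.57 and above it without shared probe sets). Proximal and distal tubule markers were higher in the same array, each by a median of 0.50.

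Tubule markers were higher in HFD, by about the same median in the proximal and the distal list. Of 25 proximal tubule markers above the floor, 22 were higher, 1 by at least 2-fold, with a median of 0.50 log2 units (1.41-fold). The organic anion transporter Slc22a6 was 2.32-fold higher, Cyp2e1 1.96-fold, the fatty acid transporter Slc27a2 1.72-fold and Slc7a13 1.66-fold. Of 15 markers of the loop, distal tubule and collecting duct, 13 were higher, with a median of 0.50 (1.42-fold). The thiazide-sensitive transporter Slc12a3 was 1.77-fold higher, Calb1 1.77-fold, Cldn8 1.74-fold and the loop transporter Slc12a1 1.64-fold. Both medians lay above all 10000 random lists. With the median over a gene's probe sets the distal median was 0.25 and the proximal one 0.50, so the 2 lists were not alike there. These lists mark cells outside the glomerular tuft, although some members, such as Cyp4b1 (12847 against 11809), had high signals on both arrays.

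Podocyte markers stood slightly lower. Of 26 above the floor, 19 were lower and 7 higher, none by 2-fold, with a median of -0.063 log2 units against a matched range of -0.00069 to 0.13. Over the 9 alternatives the podocyte median ran from -0.15 (no centring) to -0.024 (probe set median). Tubule markers (median 0.50) and myeloid markers (0.85) were higher in the same array. Dach1, a podocyte transcription factor, was 1.71-fold lower (962 against 1747, with all 3 probe sets lower), and Thsd7a, a foot process protein, 1.34-fold lower. Nes and Cd2ap differed by -0.23 and -0.20. The slit diaphragm gene Nphs1 and Podxl, a sialoprotein of the foot process surface, differed by 0.082 and -0.0029, and a second Podxl probe set by 0.23. Endothelial markers stood slightly higher, with 18 of 24 above 0 and a median of 0.18 against a matched range of -0.0061 to 0.14 (0.092 without centring). Vwf was 2.32-fold higher at a low signal (116 against 52.8), Plvap 1.41-fold, Sox18 1.31-fold and Cdh5 1.31-fold. The medians of mesangial markers (0.15, 11 genes), smooth muscle and renin cell markers (0.072, 6 genes) and parietal epithelial markers (0.085, 6 genes) lay within their matched ranges. With the median over a gene's probe sets, the parietal median was 0.56 and the mesangial one 0.20, both above their matched ranges. The largest mesangial differences were those of Fhl2 (0.46) and Mcam (0.40), and Tagln (0.68) and Acta2 (0.53) led the smooth muscle list. In the parietal list Cldn1 stood at 0.45. The adipocyte list had 4 genes above the floor, of which Car3 alone differed by 2-fold, and its median of 0.20 lay within the matched range (0.59 and above it with the probe set median). The red cell list had 2, Alas2 at a bound of 0.94 and Hba-a2 at -0.25.

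**Figure D3:**
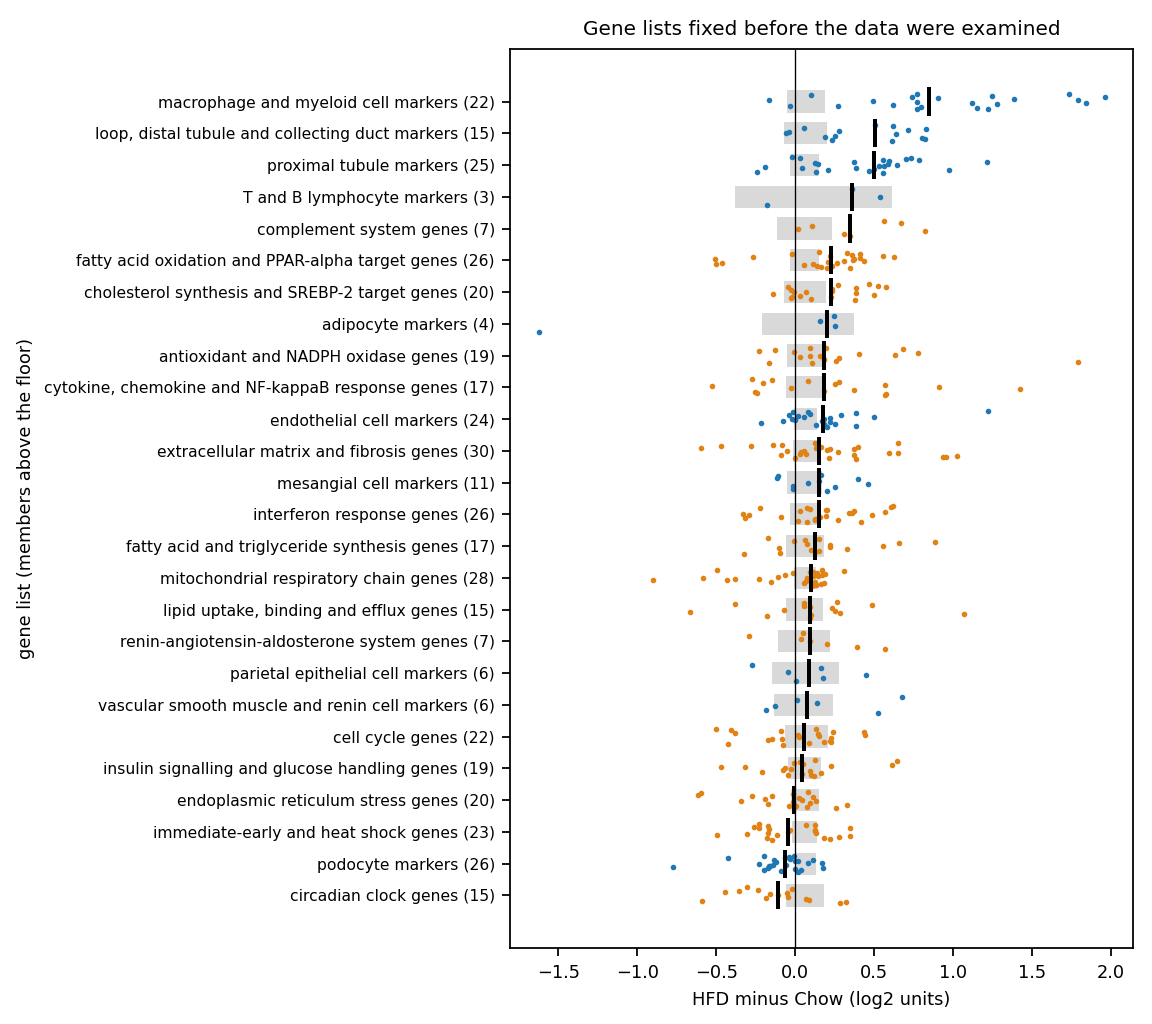
HFD minus Chow difference in log2 units (x axis) of the members of each gene list with at least 3 members above the floor (points, blue for cell type lists and orange for pathway lists), with the list median (black bar) and the central 95% of medians of 10000 random lists matched on signal (grey). Myeloid markers have the highest median (0.85), both tubule lists follow (0.50), and podocyte (-0.063) and circadian clock genes (-0.11) lie below their grey ranges.

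Members of the 4 lipid metabolism lists differed by less than 2-fold, with the exception of Cd36. Cd36, a fatty acid and oxidised lipoprotein receptor, was 2.10-fold higher (1778 against 898), and each of its 3 probe sets was at least 2-fold higher. Fatty acid oxidation and PPAR-alpha target genes were higher for 21 of 26 members, with a median of 0.23 (1.17-fold) against a matched range of -0.031 to 0.15. With the median over a gene's probe sets it was 0.13, within the matched range. Hadha was 1.54-fold and Pdk4, which restrains glucose oxidation, 1.47-fold higher, while the PPAR-alpha targets Cyp4a14 and Acot1 were 1.42-fold and 1.41-fold lower. Proximal tubule cells also express many genes of this list, and their markers were higher by 1.41-fold in the same array. Cholesterol synthesis genes were higher for 14 of 20 members, with a median of 0.23 against a matched range of -0.070 to 0.20, but it lay within the matched range in 3 of 9 alternatives (0.030 with the 70th percentile floor, 0.10 with the probe set median and 0.19 without shared probe sets). Sqle stood at 0.57, Srebf2 at 0.52, Hsd17b7 at 0.50 and Tm7sf2 at 0.47. Fatty acid synthesis genes had a median of 0.12, within the matched range, with Mlxipl at 0.88, Me1 at 0.66 and Fasn at 0.55. Lipid uptake and efflux genes as a list also lay within it (median 0.095, but 0.22 and above it with the probe set median), with Fabp3 at -0.67, Nr1h3 at 0.48 and Pltp at -0.38.

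Type IV collagen alpha-1 and alpha-2 transcripts were among the brightest genes with a difference near 2-fold. Col4a2 was 2.03-fold higher (3975 against 2075). Col4a1 was 1.91-fold higher in its brightest probe set (5687 against 3157), but its second probe set differed by -0.11 log2 units (2476 against 2835). Of 30 matrix and fibrosis genes above the floor, 22 were higher, 1 by 2-fold, with a median of 0.15 against a matched range of -0.014 to 0.14. Col3a1 was 1.94-fold and Tnc 1.57-fold higher, both at low signals, and Postn differed by -0.60. The list median lay within the matched range in 5 of 9 alternatives.

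Among inflammation genes, Il1b was 2.68-fold higher at a low signal (120 against 47.3) and Ptgs2 1.88-fold higher. Cx3cl1 stood at 0.57 and Ccl9 at a bound of 0.57. The cytokine, chemokine and NF-kappaB list as a whole had 10 of 17 genes higher and a median of 0.18, within the matched range of -0.061 to 0.19. It lay above that range in 3 of 9 alternatives (0.22 with the 30th percentile floor, 0.27 with no floor and 0.26 without shared probe sets). Complement genes were higher for 7 of 7 members, with a median of 0.35 against a matched range of -0.12 to 0.23: C2 was 1.77-fold, Cfb 1.59-fold and Serping1 1.47-fold higher, and C1ra stood at 0.35. Tubule markers (median 0.50) and myeloid markers (0.85), from cells that also make complement proteins, were higher in the same array. Antioxidant and NADPH oxidase genes had a median of 0.18, just above their matched range of -0.050 to 0.18, and within it in 6 of 9 alternatives. This list shares Cybb with the myeloid list, and without Cybb its median was 0.17, within the matched range of -0.050 to 0.17. Nox4, the oxidase of renal parenchymal cells, was 1.71-fold higher in its brightest probe set. Sod3 stood at 0.68 and Ncf1 at 0.63. Interferon response genes had a median of 0.15, within the matched range, with Xaf1 (0.62), Usp18 (0.60), Oasl1 (0.57) and Irf7 (0.49) highest.

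Circadian clock and heat shock genes stood slightly lower. Of 15 circadian genes, 11 were lower, with a median of -0.11 against a matched range of -0.057 to 0.18. Ciart, Per1 and Per2 differed by -0.59, -0.44 and -0.36, and Bhlhe40 by 0.32. Of 23 immediate-early and heat shock genes, 13 were lower, with a median of -0.049 against a matched range of -0.021 to 0.14. Split after the values were seen, 6 of 7 heat shock genes were lower (median -0.18), whereas 9 of 16 immediate-early genes were higher (median 0.095, within the matched range). Hspa1a and Hspa1b stood at -0.50 and -0.30, while Fos and Junb stood at 0.35 and 0.34. The circadian median was -0.053 with the 25th percentile added and no floor, within the matched range. Respiratory chain genes had a median of 0.097, within the matched range, and its 4 largest differences were negative: Cox6c at -0.90, Ndufb5 at -0.58, Uqcrh at -0.50 and Cox7a2 at -0.43. Endoplasmic reticulum stress genes (median -0.0059), insulin and glucose genes (0.042), renin-angiotensin genes (0.091) and cell cycle genes (0.055) lay within their matched ranges. With the probe set median the endoplasmic reticulum stress median was -0.12, below its matched range. Among them Sdf2l1 stood at -0.62 and Trib3 at a bound of -0.60, Edem1 at -0.34 (its second probe set went the other way), Slc2a4 at 0.64, Pparg at 0.61 and Irs2 at -0.47. Ace stood at 0.57, Agt at a bound of 0.39, Tpx2 at -0.50 and Mcm6 at 0.44 in its brightest probe set, with a second probe set in the other direction.

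Across the 27 lists, 9 medians lay above their matched range, 3 below and 15 within. Further probe sets of a gene gave a partial check within the arrays. For genes at least 2-fold higher and above the floor on both arrays, 18 of 20 further probe sets went the same way, and 9 of them by at least 1.5-fold. For genes at least 2-fold lower, 5 of 6 did. For genes that differed by less than 2-fold, 60.4% of further probe sets did. Small differences change sign easily, so that share is no baseline for genes picked for large ones. Such agreement concerns measurement within the 2 RNA preparations and carries no information on variation between mice.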

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

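The tests in this part were chosen after the results were seen, except the test on genomic span. For the myeloid and tubule patterns a second test was added after the outcome of the first was known, and both are given. Intervals over genes describe the lists on these 2 arrays, and none of them measures variation between mice.

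Outside the gene comparisons, of 10092 probe sets without a single gene name, 3102 were above the floor, and 22 of them were at least 2-fold higher in HFD and 30 at least 2-fold lower. The control probe set for the 3′ end of pyruvate carboxylase, a gluconeogenic enzyme, had a signal of 434 in HFD and 283 in Chow, and the Pcx gene itself was 1.51-fold higher.

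The first pattern weighed is the higher level of macrophage and MHC class II genes in HFD. A scaling or signal-dependent bias is argued against, since the lowest myeloid median under 9 alternatives was 0.76 and the highest upper end of a matched range was 0.22. Interstitial macrophages carried over with tubule fragments of fixed makeup would raise myeloid and tubule genes by 1 factor, provided that the glomeruli themselves add no signal to either. The myeloid median exceeded that of all 40 tubule markers by 0.35 (95% bootstrap interval 0.18 to 0.87). Glomerular expression of some of the 40 could lower the tubule factor and was not measured, so this gap does not decide. A high signal on both arrays, as for Cyp4b1, does not show such expression. Umod, which is in the second list below, was also bright (5000 against 3742). In the second test the myeloid median exceeded that of 21 tubule genes without known glomerular expression, listed after the values were seen, by 0.26 (0.069 to 0.66). Over the 9 alternatives this gap ran from 0.17 (without shared probe sets) to 0.62 (30th percentile floor), and was 0.58 with no floor. In the main setting the Chow values of myeloid genes such as C1qb were raised to the floor, so their differences are bounds. The second interval lay above 0, so under the condition above carry-over of fixed makeup alone would leave part of the difference over. Its lower end comes close to 0, so the size of that part is uncertain. Carry-over may still account for much, as the medians were 0.59 for the 21 tubule genes and 0.85 for myeloid markers. More leukocytes in or around the glomeruli of HFD-fed mice, carried-over tissue that was itself richer in macrophages, and differences between individual mice all stay open.

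The second pattern is the higher level of tubule markers. A larger share of tubule fragments of fixed makeup predicts 1 factor for every marker without glomerular signal. In the first test the 40 markers scattered more than matched random lists (median absolute deviation 0.26 against an upper limit of 0.20). Glomerular signal in some of the 40, which was not measured, could widen that scatter, so the test does not decide. The 21 tubule genes without known glomerular expression, listed after the values were seen, were all higher, with a median of 0.59. They ran from 0.029 (Slc5a2) to 1.21 (Slc22a6). The second test, which replaced that criterion after it had failed, compared segments alone, and the proximal minus distal difference of medians was -0.0032 (95% bootstrap interval -0.41 to 0.32), an interval too wide to weigh much. A larger tubule share with an unequal mix of segments, or with glomerular background in some markers, could give both values and stays open. So does a response of tubule genes to the diet, which was not tested.

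The third pattern is a lower level of genes that encode very small proteins, seen first as 11 of the 60 lowest genes. The lists were written after those 60 were seen and hold the 11, so that count is no support. Medians were -0.38 for 33 small respiratory chain and mitochondrial import subunits, -0.37 for 17 small ribosomal proteins and -0.24 for 30 other small proteins, such as Sec61b (-0.51) and S100a6 (-0.42). Without the members among the 60 lowest genes they were -0.32, -0.37 and -0.22. A change of respiratory chain genes as a class is argued against, since 30 large subunits and tricarboxylic acid cycle enzymes had a median of 0.15, above their matched range of -0.012 to 0.13. A loss of short transcripts in the HFD library, for example at column purification or amplification, predicts the same shift in unrelated small-protein genes, and 42 ribosomal and other genes outside the 60 lowest had a median of -0.27 against a matched range of -0.0024 to 0.13. Genomic span, the only length at hand, showed no such trend (median 0.055 in the shortest 10%, matched range 0.052 to 0.080), but span is not transcript length, so short-transcript loss stays a candidate explanation.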

How the results depend on the processing

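No paired analysis was possible because each diet has 1 array, and no array could be left out. The counts depended mostly on the floor and the threshold. With a floor at the 30th percentile, 319 genes were at least 2-fold higher and 163 lower; with no floor, 1662 and 1407; with the 25th percentile added before the log2 and no floor, 444 and 287; with a floor at the 70th percentile, 26 and 5. A threshold of 1.5-fold gave 478 and 160, and one of 3-fold 14 and 3. The median over a gene's probe sets gave 37 lower genes, of which 9 were among the 18. The other counts stayed within 1.5 times: between 62 and 79 genes were higher and between 18 and 23 lower under the 3 other scalings and the removal of shared probe sets, and 77 higher under the probe set median, of which 45 were among the 82. Dim probe sets thus limit every count, since the scatter grows toward the floor. The myeloid median was 0.76 without centring, 1.22 with the 30th percentile floor, 1.17 with no floor, 1.07 with the added percentile and no floor, and 0.94 with the probe set median. Without centring the medians were -0.15 for podocyte markers, 0.092 for endothelial, 0.42 for proximal, 0.42 for distal and 0.14 for fatty acid oxidation genes. Quantile normalization gave -0.12 for podocyte, 0.11 for endothelial and 0.17 for fatty acid oxidation genes, and loess -0.11, 0.13 and 0.18. The probe set median gave -0.024 for podocyte, 0.25 for distal and 0.13 for fatty acid oxidation genes, and removal of shared probe sets 0.58 for proximal markers. The myeloid, both tubule, complement and endothelial medians stayed above their matched ranges in 9 of 9 alternatives. The podocyte median and that of the joint immediate-early and heat shock list stayed below theirs in 9 of 9. The immediate-early genes alone had a median of 0.095 in the main setting, within the matched range. Fatty acid oxidation and circadian genes kept their place in 8 alternatives and cholesterol synthesis genes in 6. The 15 lists within their matched range in the main setting left it in 1 to 3 alternatives for 7 of them, the inflammation list in 3 and the mesangial, parietal, adipocyte, lymphocyte, lipid uptake and endoplasmic reticulum stress lists in 1 each. Reversal was counted only for named genes that differed by at least 2-fold in the main setting, and 1 gene reversed. Pnmt moved from a bound of -2.16 to 0.0062 with the 70th percentile floor, where its HFD value is raised to the floor and its Chow value lies close to it. Otherwise 60 values of single named genes moved by more than the scatter at their signal and 1036 did not. Much of this was set in advance. Changed floors leave bright genes as they were, genes under a floor on both arrays were not counted, and no centring shifts most genes by 0.083, less than the smallest scatter of 0.14. The count therefore says little about how firm single genes are. For the lists not shown here and for shifts with no value given, the cause was not tested.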

Other observations

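The tests in this part and the genes it names were chosen after the results were seen. The 82 genes at least 2-fold higher in HFD also include Cyp24a1, the vitamin D 24-hydroxylase (2.61-fold), Aldh1a2, a retinoic acid-producing enzyme (2.66-fold), Slc5a10 (2.58-fold), Tfcp2l1, a transcription factor of the collecting duct (2.55-fold), and Cldn2, the claudin of leaky tubule epithelium (2.22-fold). The sulphate transporter Slc13a1 was 3.51-fold higher in its bright probe set, while a dim second probe set differed by -0.28. Others of the 82 are Mpeg1 (2.72-fold), Ms4a6c (2.40-fold), Clec7a (2.22-fold), Ly86 (at least 2.81-fold) and Clec4a3 (at least 2.87-fold). These genes were picked because they passed 2-fold, and no test of a shared function was made. Of 7 MHC class II presentation genes above the floor, 6 were higher and 4 at least 2-fold, with a median of 1.13. H2-Ob, the member known from B cells, differed by -0.47.

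Within the respiratory chain the medians of the small and large subunit lists differed. Of 33 small respiratory chain and mitochondrial import subunits, 29 stood below 0 (the lower ones include Uqcr11 at -1.13, Atp5e at -0.81 and Atp5k at -0.67) and 4 above 0, whereas 29 of 30 large subunits and tricarboxylic acid cycle enzymes stood above 0 after centring (Uqcrc2 at 0.31, Sdha at 0.19). Without the members among the 60 lowest genes, which had suggested the pattern, 23 of 27 small subunits stood below 0, with a median of -0.32. The large-subunit median was 0.15, and the median of all genes above the floor was itself 0.064. Under the 3 other scalings the small-subunit median ran from -0.47 to -0.43 and the large-subunit median from 0.063 to 0.10, so both kept their direction.

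Basement membrane genes did not move together. Of 22, 16 stood above 0 with a median of 0.098, within the matched range of -0.029 to 0.15. Col4a2 (1.02) and the bright Col4a1 probe set (0.93) stood apart from the alpha-3, alpha-4 and alpha-5 chains of the mature glomerular basement membrane, Col4a3 (-0.17), Col4a4 (0.18) and Col4a5 (-0.31), although the probe sets of each of these 3 genes, and of Col4a1, disagreed in direction.

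Pnmt, which makes adrenaline, was above the floor in Chow only. Whether adrenal tissue carried over in the Chow library brought it was left undecided: of 12 other adrenal genes 2 were above the floor in Chow, Ddc (48.6) and Slc18a1, both less than 2-fold over the floor of 44.9, so 0 of 12 was the only count of 2-fold lower genes that the floor allowed. The Pnmt difference rests on 1 of its 3 probe sets (31.1 against 201).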
